A study of Homo sapiens with 13 samples.

How the data were processed

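Nascent transcription was measured by global run-on sequencing (GRO-seq), which labels RNA while engaged polymerases extend it in isolated nuclei, in MCF-7, an estrogen receptor positive breast cancer line. Per the labels' protocols, cells were held in G0/G1 by withdrawing hormone, in S by repeated thymidine and in M by thymidine followed by nocodazole, so each stage came with its own arrest treatment. Per the labels, each GRO-seq sample merged 2 replicates, and the deposited table held 1 column per replicate, giving 6 libraries in 3 stages with n = 2 per stage. The columns of the last stage were headed G2/M and were assigned to the M samples. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. They were kept as separate samples. The RNA-seq, H3K4me2, H3K27ac and DNase-seq samples of the series were not analysed here.

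The authors' deposited table gave whole-number scores for 21084 RefSeq genes, named with chromosome, a position and strand. The submitters' processing notes name Bowtie, TopHat2 2.1.1, HTSeq 0.5.4p3, DESeq2 1.8.2 and bedtools 2.20.1 and the build hg19, without saying which step used which. How the authors normalized and rounded these values is not given in the sources used here. They were read as normalized scores, not counts, because low values bunched at steps. In S replicate 1, 3668 genes stood at 1, 46 at 2, 927 at 3 and 39 at 4, and 3 columns held no 0. Depth in reads is therefore unknown, whole reads could not be recovered, and no interval that needs counts is given. In G0/G1, 2722 and 2606 genes stood at 0, whereas in S and M 3378 to 3668 genes stood at 1, so folds against a stage mean under 10 depend on the pseudocount and are not printed. What the position in a gene's name marks is not given, so chromosome and strand are reported without coordinates. Values were taken over genes as named, and whether counting used strand, and how reads of overlapping or near-identical genes were shared, is not given.

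The authors also deposited 3 comparison tables with log2 fold changes, their standard errors, mean scores, p-values and adjusted p-values in DESeq2's column layout, per the file headers. Their mean scores equalled the means of the normalized, rounded values after median-ratio size factors (largest relative difference 7.8e-11), so the authors' DESeq2 test had been run on those values. Results from these tables are named as the authors'.

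Before the data were examined, the comparisons, the test, 17 gene lists, the alternatives and a rule for naming genes were fixed. Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3 (linear model over all 6 libraries with stage as the only term, empirical Bayes moderation with a mean-variance trend, Benjamini-Hochberg adjustment, threshold 0.05). The 15677 genes with a mean of at least 10 over the libraries were tested. The fit had 3 residual and 13.5 prior degrees of freedom. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 17 lists, and medians of lists are given relative to the median of all genes tested. List members are counted at the threshold adjusted over all genes tested and, where it gave another count, adjusted over the list alone. Named genes were the 10 highest and 10 lowest folds per comparison among called genes with a mean of at least 50 in the higher stage and replicates that did not overlap (symbols of short or unnamed RNAs starting MIR, SNOR, SCARNA, RNU, RNY or LOC left out of the ranking), up to 4 members of each list past its set test, and 15 landmark genes. XIST is not reported here. Members that ran against the rest of a list and genes named only in the closing section's first paragraphs were chosen after their values were seen, as were PLK1, CDC25B, CDC20, FOSB, JUND, RHOB, MDM2, FAS, COL1A1, CDH5 and CD79A in the comparison of S with G0/G1.

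On simulated data of 15700 genes, of which 48 to 98 were changed by each fold in each comparison, the fit recovered 98% of 4-fold changes, 83.7% of 2-fold and 42% of 1.5-fold changes between S and G0/G1, 98%, 79.2% and 30% between M and G0/G1, and 97.9%, 81.2% and 38.8% between M and S. False calls made up 7.2%, 5.5% and 5.5% of the calls in these comparisons. The simulated libraries had no shift between stages, the same dispersion for every gene and no trend with gene density. Far fewer genes changed in them than were called in the data, so these rates check the fit and do not describe the error of the real calls.

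The alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, equal totals, equal upper quartiles, quantile normalization, the replicate number as a block, separate fits of 4 libraries, moderation without the trend or with robust weights, a minimum of 2-fold, short RNAs left out, each library left out in turn, camera with an estimated correlation, and fry. Median-ratio size factors and a correction of each library for a smooth trend on local gene density (other genes within 500 kb on either side, span 0.5), alone and with the block, were added after seeing the data. The planned tests for read counts were not run, because the values are not whole reads. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.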

Results

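GRO-seq libraries of MCF-7 cells arrested in G0/G1, S and M were compared to ask which genes are transcribed differently between stages of the cell cycle. Each stage had n = 2 replicates, and every mean ± SD of normalized values below is over those 2. The normalized values summed to 21893211 and 22084218 per library in G0/G1, 19858049 and 19999462 in S, and 20526650 and 20874805 in M. Since how these totals were set is not given, a change in all transcription between stages could not be seen. Higher, lower, rose and fell therefore refer to normalized values, not to transcription per cell. Replicates of one stage correlated across genes on the log2 scale at Pearson's r of 0.987 in G0/G1, 0.991 in S and 0.992 in M, genes not being independent replicates. Among genes with a mean of at least 100, the log2 difference between replicates had an SD of 0.164 in G0/G1, 0.184 in S and 0.180 in M.

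Of 15677 genes tested, 12498 differed between at least one pair of stages by limma (adjusted p under 0.05). The median log2 fold change of all tested genes was -0.14 for S against G0/G1, -0.11 for M against G0/G1 and 0.05 for M against S, and list medians are given relative to these shifts. Counts of list members that rose or fell are not, so they carry the shifts and depend on scaling. Some landmark genes differed between all stages by more than their replicates did. Transcription of CCNE2 (cyclin E2, an activator of CDK2 at S phase entry) was lowest in G0/G1 at 254 ± 12, highest in S at 875 ± 18.4 and between them in M at 547 ± 39.6. CCND1, the G1 cyclin D1, ran the other way, from 6472 ± 173 in G0/G1 to 3998 ± 69.3 in S and 3247 ± 308 in M, although its difference between S and M (adjusted p = 0.000969) lost its call without the filter on low values and without the mean-variance trend.

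**Figure D1:**
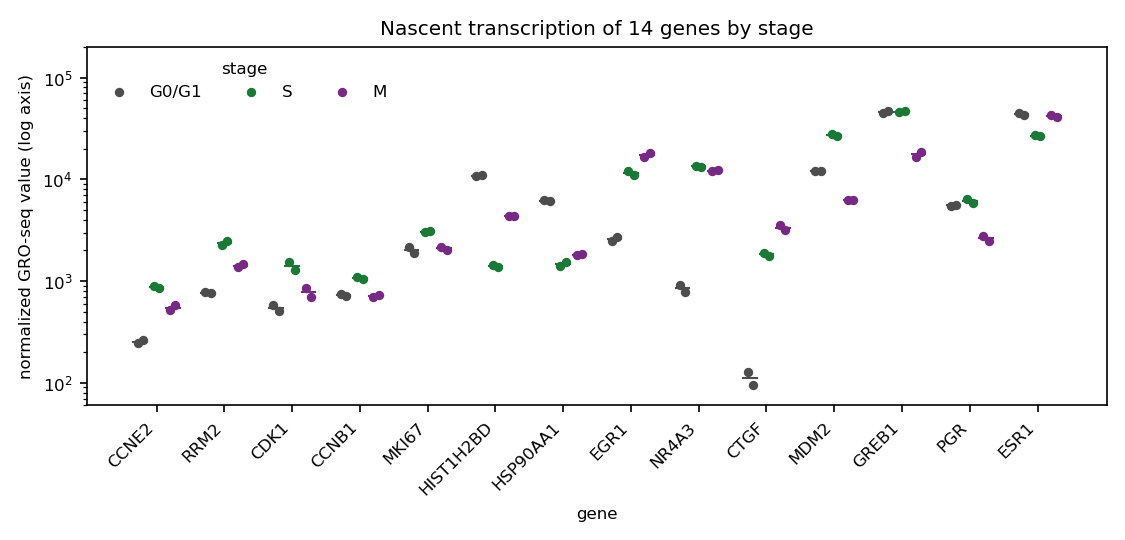
Normalized GRO-seq values (log axis) of 14 genes in G0/G1, S and M, with 1 point per replicate and a bar at the mean of the 2 replicates of each stage. CCNE2, RRM2, CDK1 and CCNB1 were highest in S, HIST1H2BD and HSP90AA1 in G0/G1, CTGF and EGR1 in M, and GREB1 and PGR were lowest in M.

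Against hormone-starved G0/G1 cells, S-arrested cells had higher normalized values for 54 of 66 genes for G1/S and DNA replication and for 61 of 78 for G2/M. Values were lower for 13 of 14 heat shock genes, 15 of 17 luminal identity genes and the 4 histone genes in the table. The calls of these lists were made by camera at its preset correlation. With an estimated correlation camera called 0 of the 17 lists (2 at an unadjusted p under 0.05). That loss alone does not show that members were correlated, since heat shock genes lost their call at an estimated correlation of -0.059. A simulated list of independent genes shifted in S also weakened, from camera p = 7.94e-49 to p = 0.000375, when the correlation was estimated. The other called lists had estimates above the preset correlation. These were 0.807 for histone, 0.263 for immediate-early, 0.229 for luminal identity, 0.183 for G1/S and 0.141 for ATF4 genes. Estimates were lower for G2/M genes (0.08), ribosomal protein genes (0.021) and YAP and TEAD targets (0.016). Correlation among members thus stays open, and p-values at the preset correlation may be too small where the estimate was higher. Fry, which asks only whether a list's genes move one way on balance, called 15. CTGF, a matrix-associated growth factor and YAP target on chromosome 6 (minus strand), rose 16.6-fold from 111 ± 24 to 1836 ± 87.0 (log2 SE 0.12, adjusted p = 6.45e-14). NR4A3, an orphan nuclear receptor gene on chromosome 9 (plus strand), rose 15.8-fold from 852 ± 95.5 to 13472 ± 159 (SE 0.07, adjusted p = 1.02e-16). The actin-bundling gene PLS3 rose 11.9-fold to 2192 ± 71.4 and PLAU, which encodes urokinase, rose 11.2-fold to 559 ± 3.54. ACTG2 (10.3-fold), EGR4 (10.2-fold), JAKMIP2 (9.02-fold), STEAP4 (8.97-fold) and CD22 (8.44-fold) followed, and GBP1 went from 4 ± 2.83 to 60 ± 11.3. BMP5, a bone morphogenetic protein gene on chromosome 6 (minus strand), fell 22.2-fold from 1297 ± 43.1 to 57.5 ± 2.12 (SE 0.16, adjusted p = 5.11e-13). TDRD1, a germline gene of the piRNA pathway, went from 185 ± 29.0 to 2 ± 1.41, the prostate-associated RNA PCGEM1 from 161 ± 5.66 to 3, and the inducible heat shock gene HSPA6 from 97.0 ± 14.1 to 2.50 ± 2.12. GUCY1A3, LCN2, GALNT5, UNC45B, SCEL and TPH2 also had means of 53 to 198 in G0/G1 and under 10 in S.

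Of 66 G1/S and DNA replication genes, 54 rose and 1 fell in S, or 55 and 1 adjusted over the list alone (relative median 0.73, camera adjusted p = 5.69e-16, adjusted p = 0.241 with an estimated correlation). RFC4, a clamp loader subunit, rose 5.00-fold to 926 ± 54.5, RRM2, a ribonucleotide reductase subunit, rose 3.05-fold to 2351 ± 156, and BARD1 (2.70-fold), E2F7 (2.67-fold) and CCNE1 (2.59-fold) rose as well. The member that fell was POLD1, from 916 to 665, a change of -0.47 (log2) that was -0.08 and not called after correction for local gene density, and that also lost its call without the filter on low values. Of 78 G2/M genes, 61 rose and 7 fell, or 61 and 8 adjusted over the list alone (relative median 0.76, camera adjusted p = 6.65e-14, adjusted p = 0.241 with an estimated correlation). KIF23, a kinesin of the spindle midzone, rose 3.75-fold to 3723 ± 120, CKS2 2.85-fold, NCAPG 2.69-fold, ANLN 2.27-fold, CDK1 2.58-fold and CCNA2 2.49-fold. CCNB1 rose 1.47-fold and MKI67 1.52-fold. Among the 7 that fell were the mitotic kinase PLK1 (858 to 291), the CDK phosphatase CDC25B (1923 to 814) and the APC/C activator CDC20 (266 to 173). Of 60 replication-dependent histone genes in the list, the table held 4, and all 4 fell (relative median -2.48, camera adjusted p = 7.69e-05, adjusted p = 0.258 with an estimated correlation). HIST1H2BD fell 7.75-fold from 10906 ± 281 to 1406 ± 24, HIST1H3D 6.33-fold, HIST1H2BK 5.93-fold and HIST2H2BE 4.05-fold. Some of these genes, HIST1H2BD and HIST1H2BK among them, are known to give polyadenylated transcripts outside S phase as well.

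Of 33 immediate-early genes, which respond to growth signals without new protein synthesis, 18 rose and 9 fell in S (relative median 0.36, camera adjusted p = 0.000228, adjusted p = 0.446 with an estimated correlation). DUSP5 rose 6.04-fold, FOSB 4.52-fold, EGR1 4.45-fold and NR4A1 3.87-fold, whereas JUND fell 2.33-fold and RHOB 2.32-fold. Of 15 YAP and TEAD target genes, 8 rose, CYR61 (4.81-fold), AMOTL1 (2.38-fold) and TGFB2 (2.03-fold) among them, and AMOTL2, AJUBA, ARHGEF17 and WTIP fell (relative median 0.70, camera adjusted p = 0.0166, adjusted p = 0.258 with an estimated correlation). This call ended after the density correction (relative median 0.80, adjusted p = 0.0523, range over 13 alternatives 0.0107 to 0.0523), and that of WTIP without the filter on low values. Ribosomal protein genes rose in 38 and fell in 11 of 76 cases (relative median 0.38, camera adjusted p = 0.000398, adjusted p = 0.241 with an estimated correlation), with RPL6 up 1.82-fold, RPS3 1.64-fold, RPS23 1.61-fold and RPL32 1.5-fold. Of 14 heat shock genes, 13 fell and HSPA4L rose from 576 to 962 (relative median -1.06, camera adjusted p = 7.69e-05, adjusted p = 0.241 with an estimated correlation). HSPA1B, an inducible HSP70 gene, fell 13.1-fold from 1693 ± 101 to 132 ± 42.4, HSP90AA1 4.20-fold, HSPH1 3.48-fold and HSP90AB1 2.18-fold. HSPA1B shares most of its sequence with HSPA1A, so its value is uncertain. Of 22 ATF4 and unfolded protein response genes, 13 fell, DDIT4 (5.18-fold), TRIB3 (3.36-fold) and SLC3A2 (2.24-fold) among them, and ATF3 (2.91-fold) and ASNS (597 to 965) rose (relative median -0.39, camera adjusted p = 0.027, adjusted p = 0.456 with an estimated correlation). This call ended without G0/G1 replicate 2 (adjusted p = 0.0566, range over 13 alternatives 0.0107 to 0.0566). Of 17 luminal identity genes, which mark the epithelial type of MCF-7, 15 fell and 0 rose (relative median -0.49, camera adjusted p = 2.67e-05, adjusted p = 0.258 with an estimated correlation), with TFAP2A down 4.05-fold, ERBB3 3.47-fold, GRHL2 1.73-fold and ESR1, the estrogen receptor gene, 1.63-fold from 43851 ± 1498 to 26867 ± 580.

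Estrogen-induced genes did not pass the set test in S against hormone-starved G0/G1, where 8 of 40 rose and 20 fell (relative median -0.07, camera adjusted p = 0.359). GREB1 stood at 45843 ± 1630 in G0/G1 and 46332 ± 920 in S, TFF1 at 4189 ± 195 and 4480 ± 104, and PGR at 5533 ± 16.3 and 6102 ± 368, with adjusted p of 0.792, 0.264 and 0.0685. These results depended on scaling. TFF1 and PGR were called higher in S under all 4 other scalings, at log2 changes of 0.17 to 0.29 and 0.21 to 0.33, and GREB1 under equal totals (0.16), quantile normalization (0.23) and median-ratio size factors (0.21). Leaving out S replicate 2 also called PGR, at 0.20, and the sign for GREB1, 0.02 as deposited, turned to -0.02 without G0/G1 replicate 1 and to -0.005 without S replicate 2. Leaving out either M replicate called PGR (0.14) and CDKN1A (-0.14) with no change in their folds. MYC (3611 ± 130 and 3365 ± 26.9, adjusted p = 0.163) and the CDK inhibitor gene CDKN1A (4878 ± 175 and 4421 ± 126, adjusted p = 0.0729) did not pass either. MYC was called lower, at -0.21 (log2), after the density correction, and CDKN1A (-0.14) and PGR (0.14) were called with the replicate number as a block and in fits of the 4 libraries alone. The p53 targets as a list did not pass (14 of 29 rose and 8 fell, 14 and 9 adjusted over the list alone, relative median 0.18, camera adjusted p = 0.108), while MDM2, which encodes the p53 ubiquitin ligase, rose 2.27-fold from 11994 ± 74.2 to 27196 ± 1134 and the death receptor gene FAS 2.67-fold. The interferon-stimulated (relative median -0.82, camera adjusted p = 0.116), NF-kB (-0.19, adjusted p = 0.404), FOXO and quiescence (-0.08, adjusted p = 0.704), cholesterol synthesis (0.10, adjusted p = 0.446) and ribosome biogenesis lists (0.18, adjusted p = 0.404) did not pass. Markers of stromal, immune and endothelial cells did not pass as a list (relative median -0.28, adjusted p = 0.704), but the endothelial cadherin gene CDH5 rose from 71.0 ± 29.7 to 556 ± 23.3, COL1A1 rose from 370 ± 78.5 to 917 ± 85.6 and the B cell gene CD79A fell from 125 ± 17.7 to 14 ± 1.41. For the FOXO and the marker lists camera pointed up while median and mean lay below 0, and for cholesterol synthesis the unshifted median (-0.04) lay below 0 and the mean (0.13) above. Of the control genes, ACTB rose 1.41-fold and GAPDH fell 2.19-fold, directions that held under the scalings tried.

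In all, 10032 genes differed between S and G0/G1, 3929 higher and 6103 lower in S (39.2% higher), and 3057 of them by at least 2-fold. The split depended on scaling, since 50.7% of calls were higher with equal totals, 44.9% with equal upper quartiles, 49.2% with quantile normalization and 54.8% with median-ratio size factors. Without the filter on low values it was 48.5%. Low genes bunched at 0 in G0/G1 and at 1 in S, so a gene at this floor in both stages can then count as higher in S.

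**Figure D2:**
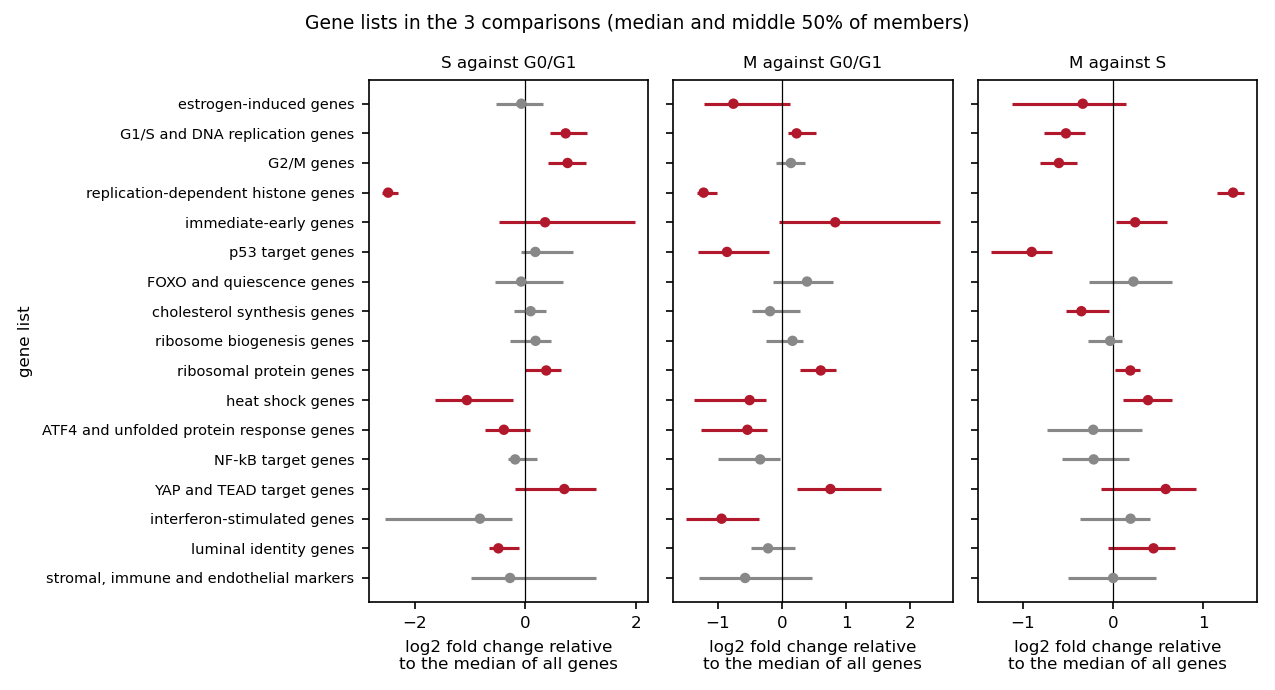
Median (point) and middle 50% (line) of log2 fold changes of the members of 17 gene lists, relative to the median of all tested genes, in each comparison; red lists passed camera at a preset correlation of 0.01 and grey lists did not. G1/S genes lay at 0.73 in S against G0/G1 and at -0.52 in M against S, and estrogen-induced genes at -0.76 in M against G0/G1.

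Against G0/G1, M-arrested cells had higher normalized values for 22 of 33 immediate-early genes, 8 of 15 YAP and TEAD targets and 52 of 76 ribosomal protein genes. Values were lower for 27 of 40 estrogen-induced genes, 24 of 29 p53 targets, 12 of 14 heat shock genes and 17 of 22 ATF4 genes. With an estimated correlation, camera called 0 of 17 lists (4 at an unadjusted p under 0.05), and fry called 14. CTGF rose 30.3-fold from 111 ± 24 to 3359 ± 261 (SE 0.12, adjusted p = 5.74e-15). ST6GALNAC5, a sialyltransferase gene on chromosome 1 (plus strand), rose 27.3-fold from 27 ± 11.3 to 735 ± 79.9 (SE 0.26, adjusted p = 9.8e-11). RIMS1 (15.3-fold), MUM1L1 (15.0-fold), NR4A3 (14.3-fold), EGR2 (13.1-fold), ASTL (12.9-fold), ATOH8 (12.7-fold) and KCNJ8 (10.9-fold) followed, and GBP1 went from 4 ± 2.83 to 69.5 ± 6.36. LINC00052, a noncoding RNA on chromosome 15 (plus strand), fell 39.5-fold from 506 ± 9.90 to 12 ± 2.83 (SE 0.27, adjusted p = 3.98e-11). KLK6, a secreted serine protease gene, fell 14.8-fold from 465 ± 58.0 to 30.5 ± 4.95, BMP5 14.7-fold to 87.5 ± 3.54 and GALNT5 14.4-fold to 14 ± 8.49. TDRD1 was at 1.5 ± 2.12 in M, and TNFSF10, LCN2, ENTPD1, GUCY1A3 and TRIM31 had means under 10 in M from 53 to 122 in G0/G1.

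Of 40 estrogen-induced genes, 27 fell and 7 rose in M (relative median -0.76, camera adjusted p = 3.96e-05, adjusted p = 0.174 with an estimated correlation). PKIB, an inhibitor of protein kinase A, fell 4.21-fold from 6147 ± 343 to 1457 ± 43.1, CELSR2 fell 3.34-fold and GREB1 2.60-fold to 17681 ± 1486. PGR (2.1-fold) and TFF1 (1.88-fold) fell as well, while EGR3, which is also an immediate-early gene, rose 4.10-fold. ESR1 stood at 43851 ± 1498 in G0/G1 and 42118 ± 1414 in M (adjusted p = 0.217). Its log2 change of -0.06 turned to 0.09 by median-ratio scaling and to 0.17 by quantile normalization, and was called lower, at -0.22, after the density correction. Its direction thus depended on the processing. Of 29 p53 targets, 24 fell, BBC3 (5.70-fold), AEN (2.59-fold), MDM2 (1.92-fold) and PPM1D (1.71-fold) among them, and CCNG1 (228 to 316) and C12orf5 (1381 to 2332) rose (relative median -0.86, camera adjusted p = 1.01e-07, adjusted p = 0.174 with an estimated correlation). The CCNG1 call, at 0.47 (log2), ended without G0/G1 replicate 1 (0.36), without M replicate 1 (0.32) and without the filter on low values. CDKN1A fell 2.26-fold. Of 33 immediate-early genes, 22 rose and 8 fell, or 23 and 8 adjusted over the list alone (relative median 0.83, camera adjusted p = 5.13e-08, adjusted p = 0.285 with an estimated correlation). EGR1 rose 6.71-fold to 17387 ± 974, FOS 5.17-fold to 19231 ± 1636 and MCL1, an anti-apoptotic gene, 5.14-fold to 26901 ± 580. Of 15 YAP and TEAD targets, 8 rose and the receptor kinase gene AXL fell from 38.5 to 14, a call that ended without the filter on low values (relative median 0.76, camera adjusted p = 3.96e-05, adjusted p = 0.154 with an estimated correlation), with CYR61 up 9.52-fold, TGFB2 4.01-fold and CRIM1 1.88-fold.

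Ribosomal protein genes rose in 52 of 76 cases in M and 3 fell, or 52 and 4 adjusted over the list alone (relative median 0.61, camera adjusted p = 1.91e-10, adjusted p = 0.154 with an estimated correlation), with RPS27A up 2.49-fold and RPL10 1.75-fold to 5288 ± 470. RPL32 (1.66-fold) and RPS23 (1.64-fold) rose as well. The 3 that fell were RPS15 (152 to 103), RPS19 (3406 to 2613) and RPS25 (374 to 282), all no longer called after the density correction alone (-0.24, -0.14 and -0.16 log2), although RPS19 was still called when the block was added, and all no longer called without the filter on low values. The RPS15 call also ended when any G0/G1 or M library was left out (-0.64 to -0.47), and the RPS25 call without G0/G1 replicate 1 (-0.39), G0/G1 replicate 2 (-0.46), M replicate 1 (-0.22) or the mean-variance trend. Neither of these 2 genes was called under any of the 4 other scalings. Of 14 heat shock genes, 12 fell and HSPD1 rose from 1558 to 1781 (relative median -0.50, camera adjusted p = 0.000404, adjusted p = 0.154 with an estimated correlation), with HSPA1B down 8.52-fold, HSP90AA1 3.4-fold, HSPH1 3.34-fold and HSPB1 1.75-fold. The HSPD1 call, at 0.19 (log2), ended when any of the G0/G1 or M libraries was left out (0.16 to 0.23), after the density correction (0.14) and without the mean-variance trend. Of 22 ATF4 and unfolded protein response genes, 17 fell, or 18 adjusted over the list alone, and ATF3 (2.27-fold), ATF4 (405 to 636) and HERPUD1 (1191 to 1989) rose (relative median -0.54, camera adjusted p = 0.00102, adjusted p = 0.288 with an estimated correlation). The amino acid transporter genes SLC7A11 and SLC7A5 fell 3.92-fold and 3.91-fold, and SESN2 2.75-fold. The 4 histone genes measured fell (relative median -1.22, camera adjusted p = 0.00102, adjusted p = 0.288 with an estimated correlation), from 3.16-fold for HIST1H2BK, 2.57-fold for HIST1H3D and 2.48-fold for HIST1H2BD to 1.48-fold for HIST2H2BE. Of 19 interferon-stimulated genes, 14 fell, or 15 adjusted over the list alone, DDX58 (2.08-fold), OAS3 (1.75-fold) and IFI27 (2.73-fold) among them, and OASL rose 3.43-fold (relative median -0.94, camera adjusted p = 0.0477, adjusted p = 0.275 with an estimated correlation). That call ended without G0/G1 replicate 2, M replicate 1 or M replicate 2. The replicate number as a block also ended it, alone (camera adjusted p = 0.0778) or with the density correction (0.0746). It held in 8 of 13 alternatives.

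G1/S genes were above their G0/G1 level in M, with 26 of 66 up and 9 down (relative median 0.23, camera adjusted p = 0.00102, adjusted p = 0.469 with an estimated correlation). RFC4 rose 4.81-fold, CCNE2 2.15-fold, CCNE1 2.07-fold, BARD1 2.04-fold and RRM2 1.83-fold. G2/M genes did not pass as a list, with 19 of 78 up and 19 down, or 18 and 18 adjusted over the list alone (relative median 0.14, camera adjusted p = 0.168). CCNA2 rose 1.86-fold and CDK1 1.41-fold, the latter not called without the filter on low values. CCNB1 (731 ± 18.4 in G0/G1, 714 ± 18.4 in M, adjusted p = 0.761) and MKI67 (2023 ± 174 and 2098 ± 101, adjusted p = 0.539) did not pass, and MKI67 changed from 0.05 (log2) to -0.03 without G0/G1 replicate 2. MKI67 was called higher by median-ratio scaling (0.21). MYC rose 1.14-fold, a call that ended without G0/G1 replicate 1 (0.16 log2), without M replicate 2 (0.12), after the density correction (0.04), without the filter on low values and without the mean-variance trend. CCND1 fell 2-fold. ACTB rose 2.24-fold, and GAPDH fell 1.37-fold, a call that ended after the density correction (-0.14). The lists for luminal identity (relative median -0.22, adjusted p = 0.0932), FOXO and quiescence (0.39, adjusted p = 0.0932), NF-kB (-0.34, adjusted p = 0.0932), cholesterol synthesis (-0.18, adjusted p = 0.454), ribosome biogenesis (0.17, adjusted p = 0.472) and stromal, immune and endothelial markers (-0.57, adjusted p = 0.744) did not pass camera, and for ribosome biogenesis the mean (-0.02) was of the other sign. The FOXO list passed without G0/G1 replicate 2 (relative median 0.47, adjusted p = 0.0454, range over 13 alternatives 0.0454 to 0.19) and the luminal list without M replicate 2 (relative median -0.3, adjusted p = 0.049, range 0.049 to 0.2). In all, 9283 genes differed, 3662 higher and 5621 lower in M (39.4% higher), and 2580 by at least 2-fold. The higher share was 47.6% with equal totals, 46.6% with equal upper quartiles, 47.8% with quantile normalization, 54.0% with median-ratio size factors and 50.1% without the filter on low values.

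In the direct comparison of M with S, 47 of 66 G1/S genes, 62 of 78 G2/M genes and 28 of 29 p53 targets were lower in M, while 11 of 17 luminal genes, 36 of 76 ribosomal protein genes and the 4 histone genes in the table were higher. With an estimated correlation, camera called 0 of 17 lists here (3 at an unadjusted p under 0.05), and fry called 13. Of 78 G2/M genes, 62 fell and 1 rose, or 65 and 1 adjusted over the list alone (relative median -0.60, camera adjusted p = 9.45e-19, adjusted p = 0.145 with an estimated correlation). MELK fell 1.93-fold, ANLN 1.92-fold from 6939 ± 265 to 3623 ± 137, CDK1 1.83-fold, ECT2 1.81-fold, AURKA 1.74-fold, CCNB1 1.5-fold and MKI67 1.46-fold. The member that rose was PLK1, from 291 ± 22.6 to 553 ± 47.4, which was still below its G0/G1 level of 858 ± 36.8. CCNA2 fell 1.34-fold, a call that ended without S replicate 1 (-0.38 log2), without M replicate 2 (-0.29) and without the filter on low values. Of 66 G1/S genes, 47 fell and 0 rose, or 51 and 0 adjusted over the list alone (relative median -0.52, camera adjusted p = 5.21e-15, adjusted p = 0.145 with an estimated correlation), with DTL down 2.26-fold, E2F7 2.13-fold, BLM 1.93-fold, WDHD1 1.91-fold and CCNE2 1.60-fold. CCNE1 (362 ± 6.36 in S, 292 ± 58.0 in M, adjusted p = 0.127) did not pass, but was called lower, at -0.52 (log2), without M replicate 2. Of 29 p53 targets, 28 fell and 0 rose (relative median -0.90, camera adjusted p = 8.65e-19, adjusted p = 0.145 with an estimated correlation). FAS fell 7.89-fold from 594 ± 0.71 to 74.5 ± 6.36, SPATA18 5.25-fold, EDA2R 4.45-fold, MDM2 4.36-fold, AEN 2.24-fold and CDKN1A 2.04-fold. Of 40 estrogen-induced genes, 24 fell and 10 rose (relative median -0.33, camera adjusted p = 5.91e-05, adjusted p = 0.145 with an estimated correlation), with PKIB down 4.53-fold, RET 4.14-fold, GREB1 2.63-fold, ELOVL2 2.42-fold, PGR 2.32-fold and TFF1 2.02-fold. Of 24 cholesterol synthesis genes, 13 fell and LSS and SC5DL rose (relative median -0.35, camera adjusted p = 0.0039, adjusted p = 0.145 with an estimated correlation). HMGCR, the rate-limiting enzyme gene of the pathway, fell 1.58-fold, HMGCS1 1.54-fold, MVK 1.5-fold and CYP51A1 1.38-fold. The SC5DL call, at 0.33 (log2), ended without S replicate 2 (0.23), M replicate 1 (0.29) or M replicate 2 (0.36) and with equal totals (0.27). Both the SC5DL and the LSS call ended without the filter on low values and without the mean-variance trend.

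The 4 histone genes rose in M against S (relative median 1.33, camera adjusted p = 2.22e-05, adjusted p = 0.166 with an estimated correlation), from 1.88-fold for HIST1H2BK to 2.46-fold for HIST1H3D, 2.74-fold for HIST2H2BE and 3.12-fold for HIST1H2BD. Of 17 luminal identity genes, 11 rose, ERBB3 (2.31-fold), GATA3 (1.71-fold), TRPS1 (1.67-fold) and ESR1 (1.57-fold) among them, and FOXA1, ELF3, CDH1 and KRT7 fell (relative median 0.45, camera adjusted p = 0.000937, adjusted p = 0.297 with an estimated correlation). Of these 4, only KRT7 was still called without the filter on low values, and FOXA1 was also not called without the mean-variance trend. Ribosomal protein genes rose in 36 and fell in 0 of 76 cases (relative median 0.19, camera adjusted p = 0.000496, adjusted p = 0.145 with an estimated correlation), with RPL28 up 1.64-fold, RPL10 1.56-fold, RPS9 1.5-fold and RPLP0 1.36-fold. Of 14 heat shock genes, 10 rose and HSPA4L fell 2.34-fold (relative median 0.39, camera adjusted p = 0.00751, adjusted p = 0.145 with an estimated correlation). HSPA8 rose 1.72-fold, a call that ended without the filter on low values, DNAJB1 1.67-fold and HSP90AB1 1.52-fold. Of 33 immediate-early genes, 17 rose, MCL1 (2.1-fold), FOS (1.68-fold) and JUN (1.55-fold) among them, and FOSL1 (2.1-fold), DUSP5, KLF10, ATF3 and IER3 fell, 6 falling when adjusted over the list alone (relative median 0.25, camera adjusted p = 0.00112, adjusted p = 0.44 with an estimated correlation). The IER3 call ended when any of 4 libraries was left out, namely either G0/G1 replicate (-0.42 log2 unchanged), S replicate 1 (-0.20) or M replicate 2 (-0.25). The same call also ended in the fit of the 4 S and M libraries alone, without the filter on low values and without the mean-variance trend. Of 15 YAP and TEAD targets, 9 rose, AMOTL2 (2.1-fold), TGFB2 (1.98-fold), CYR61 (1.98-fold) and CRIM1 (1.61-fold) among them, and AMOTL1, AXL and NT5E fell (relative median 0.58, camera adjusted p = 0.00636, adjusted p = 0.145 with an estimated correlation). MYC rose 1.23-fold, not called without the mean-variance trend, while ACTB rose 1.60-fold and GAPDH 1.60-fold, directions that held under the scalings tried.

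Among single genes, ST6GALNAC5 rose 12.1-fold from 60 ± 9.90 in S to 735 ± 79.9 in M (SE 0.26, adjusted p = 8.5e-09). SIM1 (10.1-fold), COL9A2 (8.82-fold), the Notch coactivator gene MAML2 (7.08-fold), CTNNA3 (6.88-fold), PCSK2 (6.58-fold), UGT1A1 (6.51-fold) and COLEC10 (6.41-fold) followed, AFF2 went from 8.00 ± 2.83 to 109 ± 14.1 and CYP1A1 from 6.50 ± 2.12 to 78.0 ± 1.41. UGT1A1 shares exons with other UGT1A genes, so its value is uncertain. BDKRB2, the bradykinin receptor B2 gene on chromosome 14 (plus strand), fell 9.68-fold from 4799 ± 245 to 498 ± 84.9 (SE 0.09, adjusted p = 1.65e-13). B3GNT6 (12.9-fold), the cytokine gene LIF (9.98-fold), TNFSF8 (8.68-fold), FRMPD2 (8.07-fold), CDH5 (7.83-fold), PLAU (7.83-fold) and PRDM1 (7.32-fold) fell as well, and TRIM55 went from 60.5 ± 6.36 to 4 ± 5.66, a call that ended without the filter on low values. In all, 6845 genes differed, 3801 higher and 3044 lower in M (55.5% higher), and 1332 by at least 2-fold. The higher share was 47.7% with equal totals, 56.2% with equal upper quartiles, 51% with quantile normalization and 50% with median-ratio size factors. The lists for FOXO and quiescence (relative median 0.23, adjusted p = 0.217), ATF4 (-0.22, adjusted p = 0.217), NF-kB (-0.21, adjusted p = 0.27), ribosome biogenesis (-0.03, adjusted p = 0.76), interferon-stimulated genes (0.20, adjusted p = 0.874) and stromal, immune and endothelial markers (0.003, adjusted p = 0.535) did not pass camera. For interferon-stimulated genes camera pointed down with the median and mean above 0, for the markers the mean (-0.19) lay below 0, and for ribosome biogenesis the unshifted median (0.02) lay above 0 and the mean (-0.02) below.

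The authors' deposited tables called 9808 genes between S and G0/G1 (54.0% higher in S), 9032 between M and G0/G1 (53.5% higher in M) and 6283 between M and S (54.6% higher in M) at an adjusted p under 0.05. Among the genes tested here, these tables called 9643, 8872 and 6259, of which 8274, 7694 and 6173 were also called by limma. With median-ratio size factors over all 6 libraries, the shared calls numbered 9481, 8719 and 6029. The authors' mean scores carried such factors per pair of stages. Those were 0.936 to 1.074 for S against G0/G1, 0.945 to 1.062 for M against G0/G1 and 1 for M against S. In M against S the scaling used here thus departed from the authors'. Both tests used the same libraries' values, so their overlap and shared directions are no independent support. Every shared call had the same direction. At least 2-fold changes numbered 2778, 2430 and 891 in the authors' deposited tables. The authors' folds were smaller for some low genes, as for COL9A2 in M against S (log2 2.34 against 3.14 by limma). Their 2-fold counts and those by limma are therefore not on one measure.

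Changes also differed between chromosomes. Among 11917 genes with a mean of at least 100, the median log2 change in S against G0/G1 was -0.50 on chromosome 19 and -0.37 on chromosome 16, against 0.12 on chromosomes 4 and X. In M against G0/G1 it was -0.38 on chromosome 19 and 0.19 on chromosome X. After the density correction, S against G0/G1 was at -0.17 on chromosome 19, -0.19 on chromosome 16 and lowest on chromosome 20 at -0.29. M against G0/G1 was then at -0.16 on chromosome 19 and lowest on chromosome 15 at -0.24. Across genes, which are not independent replicates, Spearman's rho with the number of genes within 500 kb was -0.28 for S against G0/G1, -0.26 for M against G0/G1 and 0.08 for M against S. Replicates of one stage also differed along this measure, with rho of -0.06 in G0/G1, -0.34 in S and -0.40 in M. On chromosome 19 the median log2 difference between replicates was -0.02 in G0/G1, -0.13 in S and -0.17 in M.

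**Figure D3:**
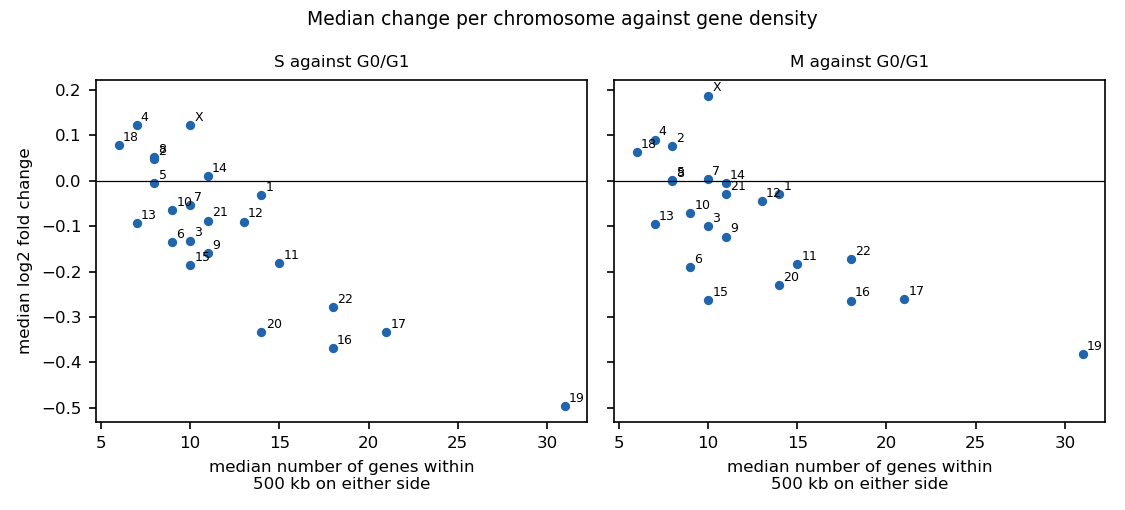
Median log2 fold change of the genes of each of 23 chromosomes (number or letter beside the point) against the chromosome's median count of genes within 500 kb on either side, for S and for M against G0/G1. Chromosome 19, with a median of 31 neighbouring genes, lies lowest in both panels at -0.50 and -0.38.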

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

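Scaling by median-ratio size factors, the gene density correction and the list tests under further scalings were chosen after the data were seen. The number of changed genes stayed within 1.5 times the main count in each comparison under every alternative but the 2-fold minimum. By its construction that minimum left 3057 (S against G0/G1), 2580 (M against G0/G1) and 1332 (M against S). In the authors' deposited tables, whose folds were smaller for some low genes, it left 2778, 2430 and 891. Leaving out each library in turn, with a lone replicate assumed to vary like the other stages, gave 8253 to 10017, 7584 to 9457 and 5334 to 6388 genes and 8 to 9, 9 to 10 and 11 list calls. The labels give replicates of different stages only a shared number. Same-numbered deviations correlated at 0.004 between G0/G1 and S, 0.014 between G0/G1 and M and 0.144 between S and M, where replicate differences also followed gene density alike (rho -0.344 and -0.401), and a block on the replicate number gave 10502, 9788 and 7525 genes. Without the filter, 10664, 9859 and 4616 of 21084 genes were called, of which 8177, 7393 and 4268 were shared with the main calls. Low genes bunched at 0 in G0/G1 and at 1 in S and M, so calls added against G0/G1 may reflect this floor. Camera with an estimated correlation called 0 lists in each comparison, and fry called 15 in S against G0/G1. Of 30 list calls, 27 kept direction and side of the threshold under the 13 other alternatives that were run on lists. The pseudocounts, filters, separate fits and other moderations were not run on lists. Equal totals, equal upper quartiles and median-ratio factors scale each library by a single factor, which hardly moves a list relative to all genes and so hardly tests it. Results for named genes kept direction and side in 251 of 282 cases over the alternatives run on them. The named genes whose sign turned had log2 changes of -0.14 to 0.05 as deposited and were not called there, and the cause was not tested. In S against G0/G1, MYC (-0.10) became 0.041 with equal totals, 0.027 with quantile normalization and 0.089 with median-ratio factors, CDKN1A (-0.14) 0.049 with median-ratio factors, and GREB1 (0.02) -0.096 after the density correction, with or without the block, with a range of -0.021 to 0.052 without single libraries. In M against G0/G1, equal totals, equal upper quartiles, quantile normalization and median-ratio factors turned CCNB1 (-0.03) to 0.053, 0.043, 0.026 and 0.118 and ESR1 (-0.06) to 0.029, 0.019, 0.166 and 0.094, and MKI67 (0.05) became -0.1 after the density correction, with or without the block, with a range of -0.034 to 0.142 without single libraries. The planned count tests were not run because the values are not whole reads. Depth is unknown, so what it limits cannot be stated in reads.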

Other observations

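Genes in this and the next paragraph were chosen after their values were seen, and the tests of explanations below, except that of random lists matched on mean value, were chosen after the result was seen. MALAT1, a nuclear noncoding RNA on chromosome 11 (plus strand), had a normalized value of 168024 ± 776 (SD, n = 2) in G0/G1 and fell 3.07-fold in S to 54754 ± 853 and 2.23-fold in M to 75467 ± 1546 (limma adjusted p = 4.12e-16 and 2.23e-14). Its neighbour NEAT1, the scaffold RNA of paraspeckles, fell 1.74-fold in S and 1.63-fold in M from 16005 ± 507. DBP, a clock-controlled transcription factor gene on chromosome 19, fell 10.0-fold in S from 1631 ± 6.36 to 163 ± 17.7 and stood at 303 ± 9.19 in M.

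SCUBE2, BMF, CYP1B1, AHRR and CYP1A1 were lower in S than in both other stages. SCUBE2 went from 2172 ± 108 in G0/G1 to 985 ± 19.8 in S and 5271 ± 91.9 in M, and the pro-apoptotic gene BMF from 734 ± 81.3 to 247 ± 23.3 and 1275 ± 70.7. CYP1B1, a target of the aryl hydrocarbon receptor, stood at 913 ± 58.7, 297 ± 8.49 and 1130 ± 85.6, and AHRR, which encodes a repressor of that receptor, at 1748 ± 21.2, 1024 ± 122 and 3177 ± 146. CYP1A1 was at 57.5 ± 21.9 in G0/G1, 6.50 ± 2.12 in S and 78.0 ± 1.41 in M, its difference between G0/G1 and M not passing (adjusted p = 0.286). UGT1A6 stood at 263 in both G0/G1 replicates, rose to 346 ± 28.3 in S and to 1413 ± 38.2 in M, but shares exons with other UGT1A genes, so its value is uncertain.

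Genes in gene-dense regions were lower in S and M than in G0/G1. On chromosome 19, the most gene-dense, the median log2 change of S against G0/G1 was -0.496 as deposited and -0.168 after the density correction, which removes such a trend whatever its source. A library trend along gene density was present between replicates, with a median difference of up to -0.17 on chromosome 19, smaller there than the change between stages. By rho with gene density across genes, replicates differed more in S (-0.344) and M (-0.401), though not in G0/G1 (-0.059). The changes of S and M against G0/G1 had rho of -0.277 and -0.255. A library trend cannot be told apart from a difference between stages, because libraries of one stage may share such a trend. Base composition was not tested, and a difference between the stages themselves stays open.

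G2/M genes were lower in M than in S although their products act in M. A difference between libraries that depends on a gene's value, left by the authors' normalization, is argued against by a relative median of -0.591 after quantile normalization, and so is the library trend with local gene density, since it was -0.595 after the correction. The list call rests on a preset correlation, and its camera adjusted p was 0.145 when the correlation was estimated. In M against S, G1/S genes and heat shock genes had the same adjusted p at estimated correlations of 0.183 and -0.059. That value therefore does not separate correlation among members from the 3 residual degrees of freedom that camera then has. Cells of other stages in the M libraries cannot be told apart from a difference in M itself, because G1/S genes had a relative median of 0.23 in M against G0/G1 and a level without such cells is unknown. A difference between the stages themselves stays open and untested, as do other effects of the authors' normalization.

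Estrogen-induced genes were lower in M than in G0/G1, the stage reached by withdrawing hormone. A difference between libraries that depends on a gene's value, left by the authors' normalization, is argued against by a relative median of -0.77 after quantile normalization, and a general fall of genes with high values in M is too, as 0 of 10000 random lists matched on mean value had a median as low as -0.87 (lowest -0.43). The list call had an adjusted p of 0.174 with an estimated correlation. An exchange of the G0/G1 and M labels could not be excluded from the G1/S genes, whose relative median of 0.23 in M against G0/G1 is small and could arise in either case, so it cannot be told apart from a correct labelling by this list. Hormone content of the medium in the S and M arrests, nocodazole itself and other effects of the authors' normalization stay open and untested.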
